A study of Drosophila melanogaster with 6 samples.

How the data were processed

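RNA of whole larvae was hybridised to Agilent Drosophila arrays in 1 colour, 1 sample per array. The labels' protocols state TRIzol extraction and Cy3-labelled cRNA made from total RNA. They also name lysis of blood cells and removal of globin messages, steps written for blood, and whether any of these was applied to larvae is not known. The scanner files hold the intensity of each spot as deposited, together with flags. Per the file headers, spots were quantified with Agilent Feature Extraction 11.5.1.1, whereas the submitters' processing notes name version 9.1. The processed signal is, by that software's definition, corrected for background within each array, and the headers do not spell out the steps. The intensities were not scaled between arrays. The authors' value table holds a linear ratio for each of 32162 probes. Compared with the scanner values, that deposited ratio matches the processed signal times 1 factor per array, divided by the median of the probe over the 6 arrays, for 75.4% of the probes (within 0.05 log2 units on every array). With spots under a signal of 5 set to 5, it matches for 94.9%, and the others were not explained. Every probe has a median of 1. Its scale is therefore linear, its centring is per probe, higher values mean more signal, and how the array factors were set is not given in the sources used here. The medians of its columns were 0.892, 1.003 and 1.066 for controls 1, 2 and 3 and 0.934, 1.171 and 0.993 for irradiated 1, 2 and 3.

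Each array has 45019 spots, of which 1417 are controls. Control spots and spots with an outlier flag (between 44 and 113 gene spots per array) were left out, and log2 of the processed signal was taken minus the 75th percentile of that array. The percentile stood at signals between 1287.5 and 1606.7. Replicate spots were averaged. A probe was kept if a share of at least 0.5 of its spots was well above background on all 3 arrays of at least 1 group, which left 23818 probes. Kept probes with the same gene name or, failing that, the same identifier were averaged into features. Of 18792 features, 12 were left out because a value was missing, and 4106 features had several probes.

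The scanner files carry identifiers but no gene symbols. Identifiers were matched without versions to accessions, symbols, locus tags and synonyms of the RefSeq gene table for the Release 6 assembly, which was used for names only, since the array design was annotated on an older assembly. Of 32162 probes, 549 matched 1 symbol (393 by accession and 156 by a name or synonym), 3 matched several and 31610 matched none. FlyBase transcript identifiers, carried by 21498 probes, were nearly all unmatched. Of the features tested, 338 had a symbol, and 46 of these had several probes. The others keep the identifier of the file.

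Samples were grouped by the dose in their titles. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no block, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 18780 features. Lists of genes with 5 or more tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Only features with a symbol could be matched to a list, so a member under an unmatched identifier is not counted. Counted this way, 19 of the 32 lists had a tested member, 13 had none and 2 were tested. The lists with none, besides those named in the results, were digestive carbohydrases and lipases, larval serum and fat body, haemocytes, testis, germ line and ovary, adult-only tissue, circadian clock and serine protease inhibitors. Where a feature was well above background on no array of a group, a bound on its fold was computed, without allowance for the spread between arrays. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the own signal of the feature and the lowest signal well above background on that array. Where the own signal is the higher on all of these arrays, the bound is the measured difference itself.

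Before the data were examined, the rule for named genes, the lists, the tests and most alternatives were fixed. The rule took the called genes of largest change, and, where fewer than 5 were called in a direction, the 10 of smallest unadjusted p, up to 4 members of each list tested, and markers of radiation response, sex and stage. Because no feature was called, the 10 of smallest p in each direction apply. They were taken among the 338 features with a symbol, since the others cannot be named, and the 2 leading identifiers in each direction are given besides. The text leaves out 1 gene that the rule took as a list member, and that gene stays in the test of its list. Of the markers, lncRNA:roX1 and lncRNA:roX2 were identified among the tested features. The text also names puc, lncRNA:Hsromega, cnc, LysE, Argk1, for, ple, epsilonTry, Jon65Aiii, gig and CG6271, chosen after their values were seen.

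The steps were tested on simulated data, on 18780 features of which 200 were changed between groups of 3 arrays. Spreads were those of these arrays, dealt at random over the features, with independent noise. Variation shared between features and any link of spread to intensity were therefore not kept. Of the changed features, 35% were recovered at 1.5-fold, 73.5% at 2-fold, 88% at 3-fold and 87.5% at 4-fold, with 2, 2, 17 and 17 false calls. With no feature changed, 0 were called. When the same changes were added to the real arrays, 31.5%, 76%, 84% and 87% were recovered. These shares hold for 200 changed features, and far fewer changed features would face a stricter cut-off.

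No 2 arrays held identical values, and the correlation over features between arrays lay between 0.9883 and 0.9958. Per the file headers, the arrays came from 2 slides. Slide 1 held the 3 controls and irradiated 1, and slide 2 held irradiated 2 and irradiated 3. Alternatives covered background correction, normalization, the filter on dim probes, the treatment of several probes, the value table, the variance model, blocks for replicate number and slide, and leaving out each array. Normexp on the mean signal was not run, because the columns of the files hold the median signal, so normexp on the median signal with an offset of 50 took its place. That alternative, the level of the roX RNAs as a covariate, the position of the array and the RNA classes of the reference table were added after the data had been seen. For the random block and the intensity trend, lists were tested with cameraPR on the moderated t. Random blocks used statmod 1.5.0, and tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.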

Results

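Gene expression was measured in whole larvae of the wild-type fruit fly strain Oregon-R (Drosophila melanogaster) on 6 one-colour microarrays. The 3 control arrays hold RNA of larvae that received 0 Gy. The 3 irradiated arrays hold RNA of larvae given 0.1 Gy of chronic gamma radiation, at 16.7 mGy/h, starting in the first larval instar. Larvae were kept 20 to a vial, and the labels give the age of both groups as 5 days. The title of the series asks whether low-dose irradiation alters gene expression and larval movement, and the comparison of the 2 groups addresses the first part of that question. Between 75.8% and 81.1% of the gene spots of each array were well above background, and no spot was saturated. The number of arrays, 3 per group, limits the precision. No label says whether replicates came from separate vials, so p-values measure only the spread between these samples.

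Among the genes that could be named, the zinc transporter gene Zip42C.2 was measured 2.25-fold higher in irradiated larvae (log2 difference 1.17 ± 0.18 SE). The non-coding RNA lncRNA:alphagamma-element:CR32865, transcribed from repeats within the Hsp70 heat shock locus, was measured 2.38-fold higher (log2 1.25 ± 0.22 SE). The gene sprint (spri), which encodes an endocytic activator of Rab proteins, was measured 1.69-fold higher (log2 0.75 ± 0.11 SE). In the other direction, LUBEL, an enzyme that builds linear ubiquitin chains, stood at 0.777 of its control level (log2 -0.36 ± 0.083 SE) and the snoRNA host gene Uhg5 at 0.807 (log2 -0.31 ± 0.082 SE). None of these differences, and no other of the 18780 features tested (338 with a gene symbol), passed an adjusted p of 0.05 in limma. The smallest adjusted p of any feature was 0.252, and those of Zip42C.2, spri and the alphagamma element were 0.297, 0.297 and 0.316.

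All 20 genes taken for the smallest unadjusted p among the named ones, 10 in each direction, had irradiated arrays that lay beyond every control array, and none passed the adjusted threshold. The choice by smallest p favours such a separation, and the groups did not overlap for 17.4% of all features. Besides the 3 above, the genes measured higher included CG6283, a predicted lipase (log2 0.77 ± 0.16 SE, 1.71-fold), and alphaTry, a digestive trypsin (0.40 ± 0.11 SE). They also included CG15533 (0.47 ± 0.13 SE), CG9759 (0.74 ± 0.24 SE) and CG32260 (0.48 ± 0.17 SE). Ost48, a subunit of the complex that adds sugars to proteins in the endoplasmic reticulum, and retn, a DNA-binding transcription factor, differed by only 0.16 ± 0.050 and 0.13 ± 0.047. Signal of spri was well above background on 2 of the 3 control arrays. The differences of the dim genes spri, CG9759 and CG32260 shrank to 0.042, 0.11 and 0.016 with another background correction (normexp on the median signal), and those of Zip42C.2 and lncRNA:alphagamma-element:CR32865 to 0.96 and 0.78, both under 2-fold. The genes measured lower, besides LUBEL and Uhg5, were Ate1, which attaches arginine to protein ends (-0.26 ± 0.058), and the J-domain chaperone gene jdp (-0.24 ± 0.060). Rab2, a GTPase of membrane traffic at the Golgi, was at -0.35 ± 0.099, and slp1, a forkhead transcription factor, at -0.28 ± 0.084. Gbs-76A, a glycogen-targeting subunit of protein phosphatase 1, was at -0.20 ± 0.054, and CG9717 at -0.32 ± 0.10. With normexp Rab2 and CG9717 shrank to -0.23 and -0.19. Another snoRNA host gene, Uhg2, was at -0.34 ± 0.10, and a U1 spliceosomal RNA at -0.22 ± 0.069.

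**Figure D1:**
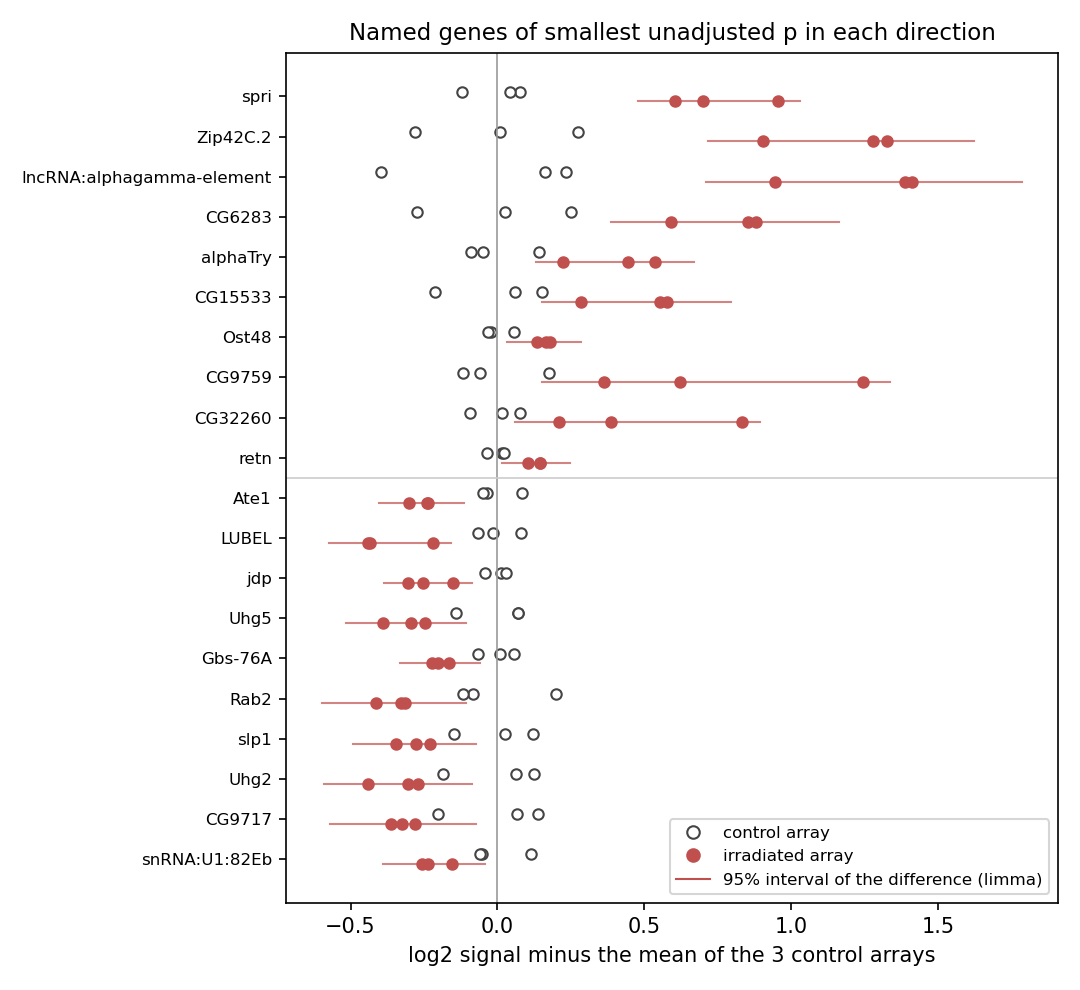
Log2 signal of each of the 6 arrays (x axis, minus the mean of the 3 control arrays) for the 10 named genes of smallest unadjusted p in each direction. Open circles are control arrays, filled circles irradiated arrays and lines the 95% interval of the difference from limma; the label lncRNA:alphagamma-element stands for lncRNA:alphagamma-element:CR32865. The groups do not overlap for any of the 20 genes, which the choice by smallest p favours, and the largest difference is 1.25.

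Only 1 irradiated array, irradiated 1, shared its slide with the controls, whereas irradiated 2 and irradiated 3 lay on another slide, so values within the shared slide rest on that array. There, irradiated 1 exceeded the mean of the controls by 1.33 for Zip42C.2, 1.41 for lncRNA:alphagamma-element:CR32865. Some differences were larger there than over all arrays, as for Ate1 (-0.30), jdp (-0.26) and CG9717 (-0.36), and others were smaller, at 0.61 for spri, 0.59 for CG6283, 0.22 for alphaTry, 0.29 for CG15533, 0.21 for CG32260, 0.20 for LysE and -0.22 for LUBEL. With slide as a fixed block, no feature passed the threshold, and 1212 features had an unadjusted p under 0.05.

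Of the 3 digestive proteases that could be named, alphaTry was higher by 0.40, which did not pass. Another trypsin, epsilonTry (0.00 ± 0.077 SE), and the chymotrypsin-like enzyme Jon65Aiii (0.02 ± 0.045 SE) lay close to 0. The 95% interval for Jon65Aiii ran from -0.090 to 0.14. LysE, a digestive lysozyme, was the only member of the antimicrobial immunity list that could be named. It was higher by 0.42 ± 0.16 SE (adjusted p = 0.492). CG6271, a predicted lipase and the last of the 3 named features that differed at least 2-fold, was 2.15-fold higher (SE 0.41 in log2 units, adjusted p = 0.479). Its value in irradiated 1 was above the control mean by 0.28, and its groups overlapped.

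Of the 27 genes on the list tied to the radiation response, 1 could be named among the tested features, so that response as a whole was not assessed. This was puc, a phosphatase gene switched on by JNK stress signalling. Its difference was 0.10 ± 0.14 SE (adjusted p = 0.866). The heat-inducible RNA lncRNA:Hsromega differed by -0.039 ± 0.13 SE, and cnc, the regulator of antioxidant genes, by -0.020 ± 0.22 SE. The TOR pathway gene gig (Tsc2) was higher by 0.17 ± 0.063 SE (adjusted p = 0.483). Few genes relevant to movement were among the tested features with a symbol, 1 of 40 on the muscle list and 2 of 71 on the neuron list. The cGMP-dependent kinase gene for, whose natural variants alter larval foraging, was at -0.18 ± 0.21 SE. Tyrosine hydroxylase (ple), the rate-limiting enzyme of dopamine synthesis, was at -0.13 ± 0.16 SE, and arginine kinase (Argk1), which buffers ATP in muscle, at 0.055 ± 0.25 SE. The 95% interval for Argk1, from -0.56 to 0.67, leaves room for changes of either sign. No member of the DNA repair, glutathione S-transferase, Turandot, glycolysis or cell cycle lists was among the tested features with a symbol. Members of these and the other lists may lie among the features without a symbol, where they could not be identified.

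Cuticle protein genes and cytosolic ribosomal protein genes were the only lists of the 32 fixed beforehand with 5 tested members. These were 5 of 148 cuticle and 5 of 92 ribosomal protein genes, and neither set of 5 shifted. The other members were not identified, so the values do not speak for the lists as a whole. RpS7, RpS3A and RpS29 were dim, with control means of -3.72, -4.46 and -4.60 relative to the upper quartile of the array. For cuticle proteins, 3 members were higher and 2 lower, with a median of 0.039 and a camera adjusted p of 0.947 (adjusted p = 0.963 with an estimated correlation). Cpr49Ag was at -0.18 ± 0.083 SE, obst-B at 0.083 ± 0.050, Cpr97Eb at -0.19 ± 0.13 and Acp65Aa at 0.29 ± 0.29. For ribosomal proteins, 2 members were higher and 3 lower, with a median of -0.060 and an adjusted p of 0.570 (adjusted p = 0.674 with an estimated correlation). RpS7 was at -0.19 ± 0.099 SE, RpS3A at -0.17 ± 0.11 and RpS29 at 0.029 ± 0.080. No member of either list was called over all features or adjusted over the list alone. In fry, which tests whether the members move on balance one way, p was 0.983 for cuticle proteins and 0.228 for ribosomal proteins.

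Among the lists with fewer named members, all 4 tested genes of mitochondrial energy supply were lower, by between -0.096 and -0.0060. Both named cytochrome P450 genes were lower, with a median of -0.088, and so were both named ecdysone response genes, with a median of -0.061. The single named genes tested were at -0.23 for the salivary glue list, -0.15 for lipid metabolism and -0.058 for amino acid and nucleotide metabolism. Those of housekeeping and of odorant-binding and taste were at -0.22 and 0.31. No member of these lists was called over all features or adjusted over the list alone. In the lists with 1 or a few named members, LysE, alphaTry and gig passed when adjusted over the list alone, which for LysE and gig is their unadjusted p.

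The sex and stage markers identified among the tested features were the 2 RNAs of the X-chromosome dosage compensation complex. These, lncRNA:roX1 and lncRNA:roX2, are made in males only. Neither passed between the groups (lncRNA:roX1 -0.20 ± 0.38 SE, lncRNA:roX2 -0.058 ± 0.37 SE; -0.88 and -0.63 with slide as a fixed block), and the 2 probes of lncRNA:roX2 disagreed in sign, at -0.23 and 0.11. Within each group they varied widely. lncRNA:roX1 was at 1.51, 1.73 and 0.83 in controls 1, 2 and 3 and at 0.48, 1.34 and 1.67 in irradiated 1, 2 and 3, in log2 units relative to the upper quartile of the array. The lowest array lay 2.39-fold below the highest. lncRNA:roX2 followed the same order at the bottom, with -2.40 in control 3 and -2.42 in irradiated 1.

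**Figure D2:**
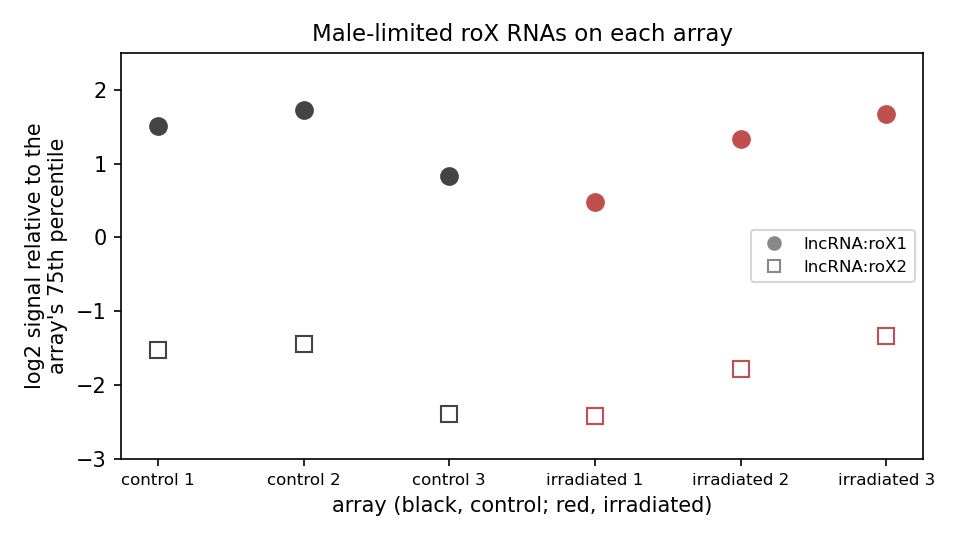
Log2 signal of lncRNA:roX1 (filled circles) and lncRNA:roX2 (open squares) on each of the 6 arrays, relative to the 75th percentile of that array; black marks are controls and red marks irradiated arrays. Control 3 and irradiated 1 are lowest for both RNAs, at 0.83 and 0.48 for lncRNA:roX1, so the spread crosses the groups.

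Over all 18780 features, limma called 0 at an adjusted p under 0.05, and none of the 338 named features passed when adjusted over these alone (smallest adjusted p 0.152). At an unadjusted p under 0.05 stood 1864 features (9.93%), 946 higher and 918 lower after irradiation, where chance alone gives 939 (5%). Over the alternatives this number ran from 763 to 2248, and another split of the same arrays gave 1974. The arrays of the groups did not overlap for 3263 features (17.4%), where chance gives 10% on average and other splits of the same arrays gave between 1006 and 2977 features. A difference of at least 2-fold was measured for 134 features, 106 higher and 28 lower, of which 92 had an unadjusted p under 0.05. That count ranged from 26 to 509 over the alternatives. The median 95% interval reached 0.22 log2 units to either side of the estimate, or 1.17-fold. Of the unnamed features, the 2 of smallest p that were higher had no control array well above background. For FBtr0302519 the measured log2 difference was 2.108 and the computed bound 1.356 (2.56-fold). EL885601 was measured 3.10-fold higher, and each of the 2 had an adjusted p of 0.252. For EL885601 the bound equals the measured difference (log2 1.634, 95% interval from 1.265 to 2.004), so its fold is an estimate and not a minimum. Both passed when the deposited value table was used instead (adjusted p 0.035). There FBtr0302519 differed by log2 1.298, which is below its bound, so that bound is not a sure minimum. The 2 of smallest p that were lower, BI573854 and CO339438, differed by -0.57 ± 0.043 SE and -0.58 ± 0.061 SE, with adjusted p of 0.252 and 0.297. In all, 50 features were well above background on every array of one group and on none of the other, 41 of them in irradiated larvae, and none of the 50 has a gene symbol here. The share of gene spots well above background also differed between arrays, from 75.8% on control 1 to 81.1% on irradiated 2. No such count was made for other splits of the arrays, so the 41 cannot be tied to irradiation.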

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

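Normexp on the median signal, the roX covariate, array position and RNA classes were chosen after seeing the data. Normexp on the mean signal was not run. Of 21 alternative settings, 20 called 0 features, and leaving out each array gave 0 to 0 features changed, higher, lower or changed at least 2-fold. The deposited value table called 7 features, 6 higher and 1 lower, all 7 at least 2-fold, FBtr0302519 and EL885601 among them, and none has a gene symbol here. In that table the array medians spread more (SD 0.143 against 0.025), the median SE was 0.19 against 0.090 and the prior degrees of freedom 7.224 against 1.576. The cause of the calls was not tested.

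Features at an unadjusted p under 0.05 numbered 1864, and 1090 with the array median, 763 with the deposited value table, 1212 with slide as a fixed block, 1046 within the slide that holds both groups and 992 with array position as a block. Leaving out each array gave between 1317 and 1827. Features at least 2-fold apart numbered 134, but 26 with normexp, 74 with probes above background on all 6 arrays, 305 with slide as a fixed block or within the slide that holds both groups and 509 with no filter on dim probes. The cause was not tested, except that the blocks and the single slide leave fewer degrees of freedom. The replicate block gave 0 calls and 1474 features. Same-numbered arrays did not deviate together (correlations of -0.266, -0.203 and -0.601 for numbers 1, 2 and 3), and no array correlated best with its own number. Deviations from the mean of a group of 3 arrays sum to 0, so these correlations are not independent. They cannot show whether same-numbered samples shared a vial or a day.

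None of the 2 tested lists shifted under any alternative in which lists were tested (all but the test per probe), and leaving out each array gave 0 to 0. With 5 RNA classes in place of the lists, 0 passed. Of 40 named genes, 32 kept their direction throughout, including the 20 of smallest p, and none of 799 values passed the threshold (lowest adjusted p 0.141). Sizes varied: with normexp spri went from 0.754 to 0.042, CG9759 from 0.743 to 0.108 and CG32260 from 0.476 to 0.016. Likewise lncRNA:alphagamma-element:CR32865 went from 1.248 to 0.781, Rab2 from -0.353 to -0.231 and CG9717 from -0.322 to -0.189. spri was not tested where all 6 arrays had to be above background. The values that changed sign belonged to small differences, the largest in size being lncRNA:roX1 at -0.197. With slide as a fixed block, and equally within the slide that holds both groups, cnc was at 0.299, lncRNA:Hsromega at 0.115, ple at 0.035, epsilonTry at -0.022, RpS29 at -0.008 and the cuticle protein median at -0.065. There lncRNA:roX1 went from -0.197 to -0.882 and lncRNA:roX2 from -0.058 to -0.630. With the deposited value table, which brings the median of all features from -0.002 to 0.091, cnc was at 0.073, lncRNA:Hsromega at 0.055, lncRNA:roX2 at 0.035 and the cytosolic ribosomal protein median at 0.033. RpS29 was at -0.067 with normexp and -0.021 with array position as a block. epsilonTry was at -0.007 with the array median and -0.002 with the roX covariate. lncRNA:roX2 was at 0.068 with that covariate and 0.109 with its brightest probe. The cause was not tested.

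Leaving out each array gave ranges that crossed 0 for Argk1 (-0.205 to 0.211), cnc (-0.180 to 0.210), epsilonTry (-0.070 to 0.058), lncRNA:Hsromega (-0.136 to 0.059), lncRNA:roX1 (-0.461 to 0.146), lncRNA:roX2 (-0.364 to 0.228), ple (-0.223 to 0.031), RpS29 (-0.040 to 0.067), the cuticle protein median (-0.028 to 0.092) and the cytosolic ribosomal protein median (-0.104 to 0.013). Other ranges kept their sign but were wide, as for puc (0.003 to 0.214), Acp65Aa (0.079 to 0.549), for (-0.337 to -0.041), LysE (0.271 to 0.525), CG9759 (0.492 to 0.932), CG32260 (0.299 to 0.609), Cpr97Eb (-0.308 to -0.095), Cpr49Ag (-0.224 to -0.110), RpS3A (-0.244 to -0.100) and Jon65Aiii (0.011 to 0.035).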

Other observations

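The tests in this part were chosen after the results were seen, except the other splits for the snRNA class, whose outcome was not known when that test was set. Several small nuclear and nucleolar RNAs were measured lower after irradiation, though none passed alone. Of 5 spliceosomal RNAs, 4 were lower, among them snRNA:U11 of the minor spliceosome at -0.41 ± 0.14 SE, snRNA:U2:34ABb at -0.25 ± 0.12 and snRNA:U1:21D at -0.22 ± 0.10, while snRNA:U12 was at 0.095 ± 0.087. Of 5 snoRNAs, 4 were lower, among them snoRNA:U3:9B, which takes part in cleavage of the ribosomal RNA precursor, at -0.24 ± 0.083. Higher were RNaseMRP:RNA, another RNA of that cleavage, at 0.13 ± 0.24 and 7SLRNA:CR32864 of the signal recognition particle at 0.16 ± 0.17. As a class of the reference table the snRNAs had a median of -0.22 and did not pass (camera adjusted p 0.0572 over 5 classes, adjusted p 0.307 with an estimated correlation). The snoRNAs had a median of -0.12 and an adjusted p of 0.181 (0.844 with an estimated correlation). A set that joined snRNAs, snoRNAs and Uhg host genes was also tried, but its members were chosen after their values were seen, so its test is void and not used. The splits are too few for a share under 0.05. For the snRNAs the real split gave the smallest camera p (0.01144, 1 of 10 splits), the next being 0.04186. The classes were added after the data had been seen, and the snRNAs had the smallest p of the 5 in the real split. This favours the real split in the ranking, so its rank is no support.

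Every test of this pattern was chosen after it had been seen: the arrays spread along an axis that crosses the groups, where the first principal component of all features, computed without the roX RNAs, held 44.6% of the variance, with scores of -12.3, -14.6 and 23.2 for controls 1, 2 and 3 and 27.2, 12.9 and -36.4 for irradiated 1, 2 and 3. Slide took 13.2% of its sum of squares and irradiation 0.29%, which argues against either as its main cause. The background handling of dim spots and the position of the arrays on their slide stay open. A candidate explanation is the share of males in each pool: the mean level of the male-limited lncRNA:roX1 and lncRNA:roX2 ordered the 6 arrays exactly against the axis (Spearman's rho -1, exact permutation p = 0.0028, the smallest that ranks of 6 arrays can give; Pearson's r -0.91, exact permutation p = 0.0083; adjusted over 6 relations 0.0056 and 0.0166), and without control 3 and irradiated 1 r was -0.91 over 4 arrays. After normexp rho was -0.829 (exact permutation p = 0.0583) and r -0.905 (exact permutation p = 0.0139). The first component of bright features alone did not follow the roX level (rho -0.486, exact permutation p = 0.3556, and r -0.374, exact permutation p = 0.4333). The roX level also went with array position, which was not tested for this axis. lncRNA:roX1 was at 1.73 and 1.67 at position 3 (control 2, irradiated 3) and 1.51 and 1.34 at position 4 (control 1, irradiated 2). It was at 0.83 at position 2 (control 3) and 0.48 at position 1 (irradiated 1), so male share and position cannot be told apart here. Testis RNA could carry the axis too. Of the testis list, 2 genes have a probe that could be named. For hale rho was -1 (r -0.998, exact permutation p = 0.0014), but it was not well above background on control 3 and irradiated 1. The other, soti, was well above background on irradiated 2 only, highest on control 3 at -7.29 and at -7.92 on irradiated 3. Testis RNA thus stays open, and the labels give no sex.

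Every test of the next pattern was also chosen after it had been seen: bright features part the groups, although no single one passed. On the first component of the 5397 features with a mean above the upper quartile of the arrays (44.8% of the variance), the controls scored between -10.4 and -2.7 and the irradiated arrays between 3.6 and 7.4, a full separation that chance gives with an exact permutation p of 0.1. With the roX level as a covariate 1932 features stood at an unadjusted p under 0.05, where chance gives 939. The roX RNAs differed little between the groups (-0.197 for lncRNA:roX1 and -0.058 for lncRNA:roX2), so the covariate had little to remove. The count also covers all features and not the bright ones alone, so it does not decide on the male share. Slide stays open, because the only irradiated array on the slide of the controls, irradiated 1, scored 10.1 above the highest of them but is 1 array, alone at its position. The position of the arrays stays open too: at the 2 positions that both groups share, the groups differed by 15.9 and 7, the latter within the range of 7.7 over the controls, and the effect of irradiation stays open with them.

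These splits were run after the results were seen. Other splits of the 6 arrays, 10 in all with the real one, are too few for a share under 0.05. Each of the 10 gave 0 features changed, 0 higher, 0 lower and 0 changed at least 2-fold, as the real one did. For lists shifted the real value was 0 and the highest other 1, so all 10 were as large. For features at an unadjusted p under 0.05 the real split gave 1864 and the highest other 1974, so 2 splits were as large. That other split sets controls 1 and 2 and irradiated 3 against the rest, as the axis that follows the roX RNAs does, with 629 features at least 2-fold apart against 134. With the roX level as a covariate, the real split gave 1932 and the highest other 1667, so 1 split was as large.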
